A study of Homo sapiens with 12 samples.

How the data were processed

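RNA from 12 cultures of H9 (WA09) cells, an established human embryonic stem cell line, was hybridised to 12 Affymetrix U133 Plus 2.0 arrays, 1 array per sample, after one-cycle labelling with biotin, per the labels' protocols. The labels put 3 arrays in each of 4 groups: unmodified cells at day 5, day 10 and day 15 of a hepatic differentiation protocol, and HNF4A knockdown cells at day 20. The series' design text speaks of independent differentiations, and the labels number the arrays of a group 1 to 3. No unmodified cells of day 20 were analysed here, so knockdown, viral transduction and culture age cannot be separated in any comparison with the knockdown cells.

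The deposited values are 1 linear intensity per probe set and array, for 54675 probe sets. GCOS is the only tool the submitters' processing notes name, without a version. The summary algorithm, the target level of any scaling and any filter are not given in the sources used here. The trimmed mean signal of the arrays ran from 94.55 to 127.9, a 1.35-fold range, so no scaling to one common level is visible in the values. No pair of arrays held identical values. The number of arrays limits the precision of every value given here, and low signals lie close to the background of the method.

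Probe sets were named through the platform annotation given with the data, which can be old. Of all probe sets, 41091 were annotated to 1 gene, 1801 to several and 11721 to none in the annotation used, and 62 were array controls. Genes were named from probe sets with a single gene. A value of 16 was added to each signal before the log2 was taken, so fold changes are on the log2(signal + 16) scale and understate changes of weak genes. The authors' scaling was kept. A probe set was kept if its signal reached the median of the whole table, 18.726, on at least 3 of the 12 arrays. This left 31417 probe sets, of which 26600 had a single gene. Each of 14157 genes was represented by its kept probe set with the highest mean. In the knockdown comparison with day 15, 1 gene had probe sets called in opposite directions. It was MBD2, named here after its values were seen.

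Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) on all 12 arrays, which share 1 estimate of the spread, with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called higher or lower at an adjusted p below 0.05 and a change of at least 2-fold. The verbs rose and fell are used of genes only for such calls. The standard errors (SE) of log2 changes come from the same fit, with n = 3 arrays per group. Gene-level adjusted p-values in the text are from limma.

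A set of 40 gene lists (liver functions, stages, other cell types and stress or signalling responses) was fixed before the data were examined, as were the tests, the alternatives in the closing section except 2, and the rule for named genes. Of 918 distinct listed genes, 647 were tested, 104 had no probe set annotated to that gene alone and 167 did not pass the filter. Lists were compared with all other genes by camera in limma, two-sided, with a preset correlation between genes of 0.01 and adjustment over all lists and the 3 main comparisons. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way without comparing them with other genes, were run as alternatives. A list counts as called at an adjusted p below 0.05 with the preset correlation. Many listed genes are on more than 1 list, so the list results are not independent.

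The rule for named genes took, for each of the 3 main comparisons, the 6 called genes with the largest rise and the 6 with the largest fall whose arrays did not overlap between the groups, passing over placeholder, antisense and sex-linked symbols. It added up to 4 called members with the largest change from each list described. It also fixed 12 genes to be named whatever their values, of which NANOG, SOX17, CXCR4, FOXA2, AFP, TTR, APOA1 and SERPINA1 are reported. The other always-named genes, HNF4A among them, are not analysed here. The planned check of the knockdown arrays' labels through the targeted gene was therefore not run.

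The test was checked on simulated values of the 14157 genes for the comparison of knockdown day 20 with day 15, with 200 genes changed. It recovered 83.0% of the genes changed by 1.5 on the log2 scale and 99.0% of those changed by 3, and called 5 unchanged genes. The simulation held no correlation between genes. The alternatives were other pseudocounts, filters, scalings and probe set rules, fits on only the groups compared, a block for the replicate number, and leaving out each array. After the data were seen, 2 alternatives were added. The reason was that 2 arrays, day 5 replicate 3 and day 15 replicate 3, had spike-in control signals unlike the others. Figures were drawn with Python 3.11.15.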

Results

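Gene expression was measured on 12 arrays during the differentiation of H9 human embryonic stem cells towards hepatocytes, the main cell type of the liver. The groups were unmodified cells at day 5, day 10 and day 15, and cells with a knockdown of HNF4A at day 20, with 3 arrays each. HNF4A is a transcription factor of liver cells. Its own level is not analysed here, so the labels of the knockdown arrays were not checked through the targeted gene. Median signals of the arrays ran from 16.1 to 24.76, and each array's mean correlation with the other arrays of its group ran from 0.940 to 0.981. The lowest belonged to day 15 replicate 3. BioDn and CreX are spike-in controls of the array. The ratio of their 3' signals, BioDn over CreX, was 0.346 on day 5 replicate 3 and 0.325 on day 15 replicate 3. It was 0.215 to 0.240 on the other arrays. The labels name no batch, and these 2 arrays are called the spike-in pair. The ratio of the 3' to the 5' ACTB control signal, which rises as RNA degrades, was 1.43 on day 15 replicate 3 and 1.17 to 1.27 on the others, while that of GAPDH was 0.949 on it and 0.961 to 1.04 on the others.

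The first comparison asks what changed between day 5 and day 10. APOA1, the main protein of high-density lipoprotein, rose 115-fold, from a signal of 32.02 ± 17.33 to 5504 ± 1948 (SD, n = 3; log2 change 6.85 ± 0.32 SE, adjusted p = 2.29e-08). Without probe sets whose names end in _x_at or _s_at, APOA1 was read from another probe set, with 1.04 and an adjusted p of 0.086 (range over alternatives 1.18e-08 to 0.086). APOB, the main protein of low-density lipoprotein, rose 31.2-fold. IGFBP3, which binds insulin-like growth factors, rose 79.1-fold, and EPAS1, a hypoxia-inducible transcription factor, rose 33.9-fold. CST2, a secreted cystatin, and SYTL5 rose 56.5-fold and 48.0-fold. Over the same days LEFTY1 and CER1, secreted inhibitors of NODAL signalling, fell 167-fold (log2 change -7.38 ± 0.43 SE, adjusted p = 1.65e-07) and 119-fold. MIXL1, a mesendoderm transcription factor, fell 34.7-fold, CALB1 20.5-fold, NODAL itself 20.4-fold and FREM1 15.9-fold.

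Of 14157 genes tested, 884 were called between these days, 563 higher and 321 lower at day 10. Of the 23 tested genes of the pluripotency list, 11 were lower and none higher (15 lower when adjusted over the list alone), with a median log2 change of -1.42. Camera gave an adjusted p of 2.11e-11, and an adjusted p = 0.378 with an estimated correlation, the highest of a range over alternatives that began at 1.27e-17. GAL, a neuropeptide abundant in stem cells, fell 15.8-fold, GDF3 6.72-fold and FGF4 5.28-fold. NANOG, a core transcription factor of pluripotent cells, fell 14.6-fold (log2 change -3.87 ± 0.94 SE, adjusted p = 0.0177). The NANOG call was lost without any one of 5 arrays, which were day 5 replicates 1, 2 and 3 and day 10 replicates 1 and 2 (adjusted p from 0.051 to 0.085), and with a pseudocount of 1 (0.133; range over alternatives 0.000458 to 0.133). The NANOG difference was 9.39-fold without day 10 replicate 1 and 22.7-fold without day 10 replicate 3. Of the 13 genes of the primitive streak and mesendoderm list, 4 were lower, among them GSC by 14.4-fold (list adjusted p = 0.00158, and adjusted p = 0.428 with an estimated correlation, range from 0.000121). When adjusted over the list alone, 4 were lower and 2 higher. The 29 genes of the definitive endoderm list held 9 lower and 3 higher (10 and 3 adjusted over the list alone), at a list adjusted p of 0.0022, and an adjusted p = 0.429 with an estimated correlation, range from 0.000145. FGF17 fell 9.89-fold and CYP26A1, which degrades retinoic acid, 7.82-fold (4.96-fold without day 10 replicate 1). SOX17 and CXCR4, nuclear and surface markers of definitive endoderm, were not called, with log2 changes of -0.83 ± 0.57 and -0.99 ± 0.46 SE.

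Some of the liver lists were higher at day 10. Of 16 genes of lipid transport, 5 were higher and none lower (6 higher adjusted over the list alone), with a median log2 change of 0.97. The list adjusted p was 5.21e-07, and adjusted p = 0.378 with an estimated correlation, range from 2.59e-14. MTTP, which loads lipid onto APOB, rose 11.9-fold (24.4-fold without day 10 replicate 3) and APOA2 8.30-fold (5.26-fold without day 5 replicate 2). The hepatoblast list held 6 higher of 15 genes (7 higher and 1 lower adjusted over the list alone; list adjusted p = 4.31e-05, and adjusted p = 0.277 with an estimated correlation, range from 3.02e-07), with KRT19 up 5.23-fold and KRT8 up 3.72-fold, both keratins of simple epithelia. The hepatoblast list was not called without _x_at and _s_at probe sets (adjusted p = 0.175). Lists of other epithelia were called with it. Biliary epithelium held 5 higher and none lower of 15 genes (list adjusted p = 9.05e-06, and adjusted p = 0.341 with an estimated correlation). Intestinal epithelium held 2 higher and none lower of 13 (list adjusted p = 0.0152, and adjusted p = 0.388 with an estimated correlation). The coagulation list was also called (5 higher and 1 lower of 15, likewise adjusted over the list alone; list adjusted p = 0.00356, and adjusted p = 0.429 with an estimated correlation, range from 1.1e-06), but not with fry (0.0815). So were the classical HNF4A-site genes (6 higher and none lower of 19, likewise adjusted over the list alone; list adjusted p = 0.000174, and adjusted p = 0.388 with an estimated correlation, range from 7.09e-08). The other liver lists were not called. Adjusted p was 0.0786 for plasma proteins, 0.21 for bile acids, 0.632 for complement, 0.703 for cholesterol and 0.714 for hepatic transcription factors. It was 0.797 for the urea cycle, 0.835 for cytochromes P450, 0.924 for peroxisomes and 0.963 for glucose metabolism. TTR, a plasma carrier of thyroid hormone, rose 12.3-fold (log2 change 3.62 ± 0.93 SE, adjusted p = 0.0246). This call was lost without day 5 replicate 2 or 3 or day 10 replicate 1 or 2 (adjusted p from 0.0666 to 0.134), and with a pseudocount of 64 (0.0582; range over alternatives 0.0013 to 0.134). The TTR difference was 7.37-fold without day 10 replicate 2 and 21.1-fold without day 10 replicate 3. AFP, SERPINA1 and FOXA2 were not called, with log2 changes of 1.30 ± 0.92, 0.14 ± 1.03 and 0.76 ± 0.41 SE.

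The mesenchyme and stellate list held 10 higher and 2 lower of 30 genes (16 and 3 adjusted over the list alone), with a median log2 change of 1.44. The list adjusted p was 1.2e-05, and adjusted p = 0.429 with an estimated correlation, range from 1.46e-08. SNAI2, a transcription factor of mesenchymal cells, rose 9.19-fold and LUM, a matrix proteoglycan, 9.99-fold. On day 5 replicate 3 the LUM signal was 12.27, against 408.8 and 316 on the other day 5 arrays. Without that array the rises were 4.22-fold for LUM and 5.20-fold for SNAI2, and without day 5 replicate 1 LUM rose 16.3-fold. Without _x_at and _s_at probe sets the LUM change was 1.65 and not called (adjusted p = 0.0593, range over alternatives 0.00055 to 0.0593). Fry did not call the mesenchyme and stellate list (adjusted p = 0.0886). Of 30 genes of the epithelial junction list, 6 were higher and none lower (7 higher adjusted over the list alone; list adjusted p = 1.47e-07, and adjusted p = 0.378 with an estimated correlation, range from 4.89e-10). They included CLDN4, a tight junction protein, up 3.90-fold, and PKP2, up 2.65-fold. The 15 constitutive control genes held no limma call in any of the 3 main comparisons, and none when adjusted over the list alone; 3 of them had an unadjusted p below 0.05 in each comparison.

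**Figure D1:**
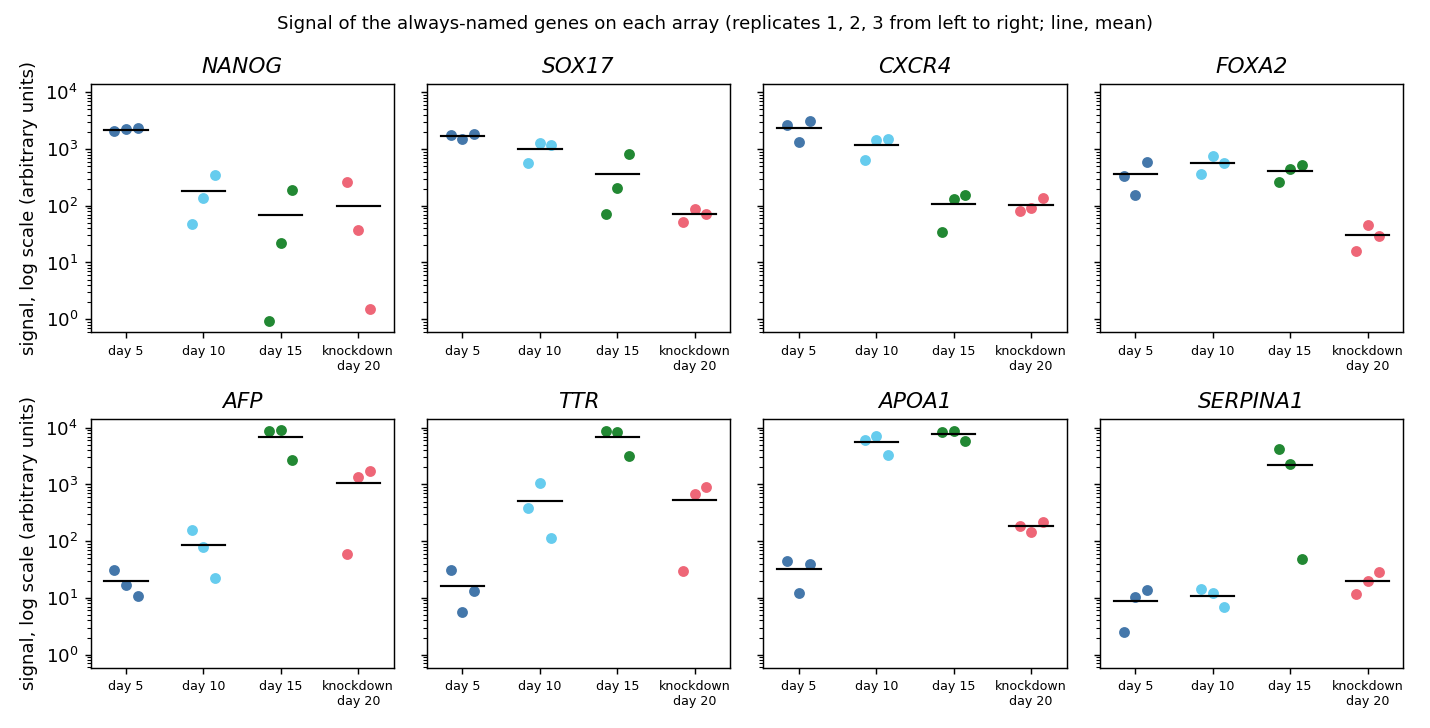
Signal of 8 genes on each of the 12 arrays, on a log axis in arbitrary units; points are arrays (replicates 1, 2 and 3 from left to right in each group) and lines are group means. AFP stood at 8853, 9000 and 2714 on the day 15 arrays, and at 59.77, 1363 and 1762 on the knockdown arrays.

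Between day 10 and day 15 AFP, the main plasma protein of fetal liver, rose 71.0-fold, from 84.85 ± 66.34 to 6856 ± 3588 (SD, n = 3; log2 change 6.15 ± 0.92 SE, adjusted p = 0.0014). FGG and FGB, chains of fibrinogen, rose 64.6-fold and 56.5-fold, AHSG, a plasma glycoprotein, 59.3-fold and RBP4, the plasma carrier of retinol, 54.7-fold. SLN, a regulator of the calcium pump of muscle, rose 38.5-fold. The cystatins CST2, CST1 and CST4 fell 45.9-fold, 19.8-fold and 15.3-fold. EOMES, a transcription factor of mesendoderm, fell 19.5-fold, DUSP6, a feedback inhibitor of ERK signalling, 17.0-fold and TNFRSF11A 15.5-fold. Single arrays moved several of these folds. Without day 15 replicate 3 AHSG rose 241-fold, FGG 132-fold and RBP4 106-fold, and CST1 fell 30.8-fold. Without day 15 replicate 1 AHSG rose 26.7-fold, and CST2 and CST1 fell 20.7-fold and 11.1-fold. AHSG rose 32.4-fold and CST2 fell 75.8-fold without day 15 replicate 2. FGB rose 107-fold without day 10 replicate 1 and 27.6-fold without day 10 replicate 3.

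In this comparison 718 genes were called, 447 higher and 271 lower at day 15. The count was 352 without day 10 replicate 3. It was 1085 without the spike-in pair, an alternative chosen after seeing the data. Of the 20 plasma protein genes, 10 were higher and 1 lower (14 and 1 adjusted over the list alone), with a median log2 change of 1.61. The list adjusted p was 4.51e-10, and adjusted p = 0.378 with an estimated correlation, range from 3.35e-18. AGT, the precursor of angiotensin, rose 34.5-fold and SERPINA1, the inhibitor of neutrophil elastase, 32.2-fold. Day 15 replicate 3 was lower than the other day 15 arrays in several of these genes. SERPINA1 read 4254, 2313 and 48.61 on day 15 replicates 1, 2 and 3, RBP4 5277, 4866 and 677.7, and AHSG 5738, 3874 and 54.42. Without day 15 replicates 1, 2 and 3 in turn SERPINA1 rose 14.5-fold, 19.6-fold and 118-fold, and AGT rose 21.5-fold without replicate 1 and 77.2-fold without replicate 3. TTR rose 16.3-fold further (log2 change 4.03 ± 0.93 SE, adjusted p = 0.0173), a call lost without day 10 replicate 3 or day 15 replicate 1 or 2 (adjusted p from 0.0595 to 0.095; range over alternatives 0.00105 to 0.095). The TTR difference was 27.3-fold without day 10 replicate 2 and 9.53-fold without day 10 replicate 3. APOA1 and FOXA2 were not called, with log2 changes of 0.54 ± 0.32 and -0.45 ± 0.41 SE.

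Other liver lists held smaller numbers of calls. The lipid transport list held 3 higher and none lower of 16 genes (6 higher adjusted over the list alone; list adjusted p = 7.43e-05, and adjusted p = 0.394 with an estimated correlation, range from 2.57e-08), but was not called with fry (0.0815). FABP1, a fatty acid carrier, rose 12.9-fold. APOC3, an apolipoprotein, rose 13.2-fold, a call lost without day 10 replicate 2 or 3 or day 15 replicate 1 or 2 (adjusted p from 0.0608 to 0.102; range over alternatives 1.45e-05 to 0.102). The coagulation list held 7 higher and none lower of 15 genes (9 higher and 1 lower adjusted over the list alone; list adjusted p = 9.62e-05, and adjusted p = 0.378 with an estimated correlation, range from 9.47e-08), with PLG, the precursor of plasmin, up 11.5-fold. Of 12 genes of bile acid synthesis and transport, 5 were higher and none lower, and likewise when adjusted over the list alone (list adjusted p = 0.00665, and adjusted p = 0.378 with an estimated correlation, range from 7.74e-06). AKR1D1, a reductase of bile acid synthesis, rose 15.8-fold and SLCO2B1, an organic anion carrier, 7.17-fold. The list of cytochromes P450 and conjugating enzymes held 5 higher and none lower of 22 genes, also when adjusted over the list alone (list adjusted p = 0.0098, and adjusted p = 0.378 with an estimated correlation, range from 0.00143). Its called members were led by AKR1D1, GSTA1 (14.1-fold) and SULT1E1 (7.62-fold). This list was not called without day 10 replicate 2 (adjusted p = 0.0508) or with a stricter filter (0.124). Day 15 replicate 3 was again the lowest of its group, with AKR1D1 at 978.1, 1304 and 421.5 on replicates 1, 2 and 3, PLG at 517.6, 249.9 and 46.55, and GSTA1 at 2080, 2240 and 420.4. Without it APOC3 rose 37.3-fold, FABP1 27.5-fold, GSTA1 24.2-fold, PLG 20.9-fold and SULT1E1 11.8-fold. Without day 15 replicate 1 FABP1 rose 6.49-fold and PLG 7.16-fold, and APOC3, which was not called, stood 5.40-fold higher. Without day 10 replicate 3 AKR1D1 rose 9.97-fold and GSTA1 8.55-fold. The classical HNF4A-site list held 9 higher and none lower of 19 (list adjusted p = 1.92e-08). Peroxisome and fatty acid oxidation held 4 higher and none lower of 22 (list adjusted p = 9.62e-05). The urea cycle list held 6 higher and 1 lower of 22 (list adjusted p = 0.032). Complement was called with no called gene among 11 (list adjusted p = 0.0115), but not with fry (0.0886). With an estimated correlation these 4 had adjusted p = 0.378, 0.429, 0.411 and 0.388. The lists of hepatic transcription factors, hepatoblast markers, glucose metabolism and cholesterol biosynthesis were not called (list adjusted p = 0.159, 0.298, 0.7 and 0.703).

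Lists of other cell types were called in the same comparison. The intestinal epithelium list held 2 higher and none lower of 13 (3 higher adjusted over the list alone; list adjusted p = 0.0114, and adjusted p = 0.388 with an estimated correlation, range from 0.00284). MEP1A, a brush border protease, rose 11.8-fold and CDX2, an intestinal transcription factor, 2.63-fold. The CDX2 call was lost without day 10 replicate 3 (adjusted p = 0.0717), with a pseudocount of 1 (0.0641) and, at under 2-fold, with one of 64 (range over alternatives 0.00499 to 0.0717). The mesenchyme and stellate list held 2 higher and none lower of 30, also when adjusted over the list alone (list adjusted p = 0.0218, and adjusted p = 0.734 with an estimated correlation, range from 3.71e-07). DCN, a matrix proteoglycan, rose by 3.46 on the log2 scale and COL5A2, a fibrillar collagen, rose 2.32-fold, the latter call lost without day 10 replicate 3 (adjusted p = 0.0574, range over alternatives 7.59e-05 to 0.0574). The list was not called without day 10 replicate 2 (0.0676) or day 15 replicate 1 (0.35), or with fry (0.442).

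Of 29 definitive endoderm genes, 10 were lower and 1 higher (13 and 2 adjusted over the list alone; list adjusted p = 0.000193, and adjusted p = 0.388 with an estimated correlation, range from 6.38e-09). CXCR4, a chemokine receptor, fell 10.4-fold and TRPA1, an ion channel, 9.32-fold, while VTCN1, an inhibitor of T cells, rose 7.20-fold. Fry did not call this list (adjusted p = 0.0559). SOX17 had a log2 change of -1.95 ± 0.57 SE (adjusted p = 0.0501). Without day 15 replicate 3, where its signal was 825.4 against 70.4 and 203.6, that change was -2.82 with an adjusted p of 0.000348. It also passed without day 10 replicate 1 (adjusted p = 0.0443) and without knockdown replicate 1 (adjusted p = 0.0485), with the spike-in pair as a block (-2.41, adjusted p = 0.00702) and under several other settings (range over alternatives 0.000348 to 0.173). The FGF and MAPK response list held 10 lower and 2 higher of 21 genes (12 and 2 adjusted over the list alone), with a median log2 change of -1.25. Its adjusted p was 1.19e-08, and adjusted p = 0.286 with an estimated correlation, range from 1.09e-11. SPRY4 and DUSP4, both feedback inhibitors of the pathway, fell 6.94-fold and 4.76-fold, and KLB, a co-receptor of endocrine FGFs, rose 10.2-fold. Of 32 cell cycle genes 3 were lower and none higher (4 lower adjusted over the list alone), at a median log2 change of -0.77 and a list adjusted p of 1.14e-11, with adjusted p = 0.388 with an estimated correlation, range from 2.68e-17. MCM7, a subunit of the replicative helicase, fell 2.25-fold. Fry did not call the cell cycle list (adjusted p = 0.059). NANOG was not called (log2 change -1.59 ± 0.94 SE).

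Over the whole course from day 5 to day 15, AFP, TTR, APOA1 and SERPINA1 rose, with log2 changes of 7.44 ± 0.92, 7.65 ± 0.93, 7.39 ± 0.32 and 5.15 ± 1.03 SE. NANOG, SOX17 and CXCR4 fell, with log2 changes of -5.46 ± 0.94, -2.78 ± 0.57 and -4.37 ± 0.46 SE. FOXA2, a transcription factor of endoderm and liver, was not called (0.32 ± 0.41 SE). Without _x_at and _s_at probe sets the APOA1 change was 1.35 (adjusted p = 0.0102, range over alternatives 3.19e-09 to 0.0102). Without day 15 replicates 1, 2 and 3 in turn SERPINA1 rose 15.9-fold, 21.5-fold and 129-fold, against 35.4-fold with all arrays. Without replicate 1 and without replicate 3 NANOG fell 25.4-fold and 88.0-fold, against 44.0-fold, and SOX17 fell 4.02-fold and 12.5-fold, against 6.86-fold. In all, 2237 genes were called, 1344 higher and 893 lower at day 15. With the spike-in pair as a block the count was 2294, and without both of its arrays it was 2631. Of the 2631 genes called on the other 10 arrays, 2467 had the same sign within the pair, 1 array against 1 (93.8%).

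Among the unmodified stages, 231 genes were highest at day 5, 70 at day 10 and 386 at day 15, each called against both other stages. LEFTY1, CER1 and MIXL1 led those of day 5, CST2, CST1 and CST4 those of day 10, and AFP, FGG and AHSG those of day 15. Single arrays moved these counts. The day 10 count was 36 without day 10 replicate 2. The day 15 count was 195 without day 10 replicate 3, 238 without day 15 replicate 2 and 627 without day 15 replicate 3, and it was 655 without the spike-in pair.

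The knockdown cells of day 20 were compared first with unmodified cells of day 15, the nearest stage. RBP4 fell 66.5-fold, from 3607 ± 2545 to 27.35 ± 20.11 (SD, n = 3; log2 change -6.06 ± 0.63 SE, adjusted p = 7.9e-05). APOA2 fell 61.4-fold, APOB 56.7-fold, APOC3 44.5-fold, AHSG 39.6-fold and APOA1 39.0-fold (log2 change -5.29 ± 0.32 SE, adjusted p = 1.47e-06). The AHSG call was lost without day 15 replicate 2 (adjusted p = 0.0508) and with only the groups compared in the fit (0.0567; range over alternatives 2.57e-09 to 0.0567). Without _x_at and _s_at probe sets the APOA1 change was -1.16 and not called (adjusted p = 0.0608, range over alternatives 2.88e-07 to 0.0608). MGP, an inhibitor of calcification, rose 26.4-fold (log2 change 4.73 ± 0.80 SE, adjusted p = 0.00253), COL15A1, a basement membrane collagen, 23.6-fold and DPT, dermatopontin, 12.5-fold. EGFL6 rose 13.3-fold, a call lost without knockdown replicate 2 or 3 (adjusted p = 0.0615 and 0.0649) and with only the groups compared (0.0665; range over alternatives 0.000205 to 0.0665). DIO3, which inactivates thyroid hormone, rose 12.8-fold and IL1R1, the interleukin 1 receptor, 8.32-fold. Knockdown replicate 1 was lower than the others in MGP, with 145.3 against 1747 and 1948, and in COL15A1, with 520.6 against 2983 and 2873. Without it the rises were 59.8-fold for MGP, 41.6-fold for COL15A1, 30.6-fold for EGFL6, 23.6-fold for DIO3 and 23.4-fold for DPT. Without knockdown replicate 3 MGP rose 17.1-fold and DPT 8.35-fold, and the EGFL6 difference without knockdown replicate 2, which was not called, was 8.13-fold. Without day 15 replicate 3 AHSG fell 161-fold, RBP4 129-fold, APOC3 126-fold and APOB 99.0-fold, and COL15A1 and EGFL6 rose 13.8-fold and 7.39-fold. Without day 15 replicate 1 APOC3 and AHSG fell 18.2-fold and 17.8-fold, and COL15A1 and EGFL6 rose 37.1-fold and 20.7-fold. The AHSG difference without day 15 replicate 2, which was not called, was 21.7-fold. Knockdown, viral transduction and age differed together in this comparison, as no unmodified cells of day 20 were analysed here.

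Here 726 genes were called, 264 higher and 462 lower in the knockdown cells, and the count was 470 without knockdown replicate 3. Of 33 liver genes chosen in advance as classical carriers of HNF4A sites, 19 were tested. Of these 13 were lower and none higher, and likewise when adjusted over the list alone. The median log2 change was -4.29, the list adjusted p was 4.59e-14, and adjusted p = 0.277 with an estimated correlation, range from 5.62e-23. Of its 19 tested genes, 18 are also on another list. Of 16 lipid transport genes 10 were lower and none higher, also when adjusted over the list alone, with a median log2 change of -3.36 (list adjusted p = 2.11e-11, and adjusted p = 0.341 with an estimated correlation, range from 2.17e-21). Of 20 plasma protein genes 11 were lower and none higher (13 lower and 1 higher adjusted over the list alone), with a median of -1.39 (list adjusted p = 4.72e-10, and adjusted p = 0.378 with an estimated correlation, range from 1.2e-19). AGT fell 27.9-fold. SERPINF1, an inhibitor of angiogenesis, was not called (1.59 ± 0.68 SE, adjusted p = 0.19), with mean signals of 634.7 at day 15 and 2531 in the knockdown cells. The complement list, also of secreted proteins, was not called either (list adjusted p = 0.966). SERPINA1 fell 24.3-fold (log2 change -4.60 ± 1.03 SE, adjusted p = 0.0144), a call lost without day 15 replicate 1 or 2 (adjusted p = 0.0549 and 0.0672) and with only the groups compared (0.0733; range over alternatives 2.05e-08 to 0.0733). TTR fell 20.1-fold, with -4.33 ± 0.93 SE. AFP fell 10.6-fold (log2 change -3.40 ± 0.92 SE, adjusted p = 0.0383), a call lost without any one of 6 arrays, which were day 5 replicates 1 and 2, day 10 replicate 2, day 15 replicates 1 and 2 and knockdown replicate 1 (adjusted p from 0.0517 to 0.113). That call was also lost with a pseudocount of 1 (0.0627), no filter (0.0589) and only the groups compared (0.104; range over alternatives 0.0217 to 0.113). Without knockdown replicates 1, 2 and 3 in turn AFP stood 3.85-fold, 16.4-fold and 18.6-fold lower, and TTR fell 7.79-fold, 30.4-fold and 34.4-fold. Without day 15 replicates 1 and 3 in turn SERPINA1 stood 10.9-fold and 88.8-fold lower, and AGT fell 17.4-fold and 62.5-fold. SERPINA1 was 14.8-fold lower without day 15 replicate 2.

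Lists of hepatic transcription factors, bile acids, amino acid breakdown and coagulation were lower as well. Of 17 hepatic transcription factors 6 were lower and none higher, also when adjusted over the list alone (median log2 change -0.77, list adjusted p = 1e-04, and adjusted p = 0.378 with an estimated correlation, range from 1.11e-05). FOXA2 fell 9.22-fold (log2 change -3.21 ± 0.41 SE, adjusted p = 0.00037), CEBPA 7.39-fold, FOXA3 3.99-fold and NR5A2 2.51-fold. With a pseudocount of 64 the NR5A2 change was -0.70, below 2-fold (adjusted p = 0.00525, range over alternatives 0.000356 to 0.035). Of 12 bile acid genes 7 were lower and none higher, also when adjusted over the list alone (list adjusted p = 1.56e-06, and adjusted p = 0.277 with an estimated correlation, range from 2.18e-12). AKR1D1 fell 25.2-fold, SLCO2B1 9.60-fold and ABCC2, a canalicular export pump, 4.71-fold. Of 22 genes of the urea cycle and amino acid breakdown 6 were lower and none higher (7 lower adjusted over the list alone; list adjusted p = 1.95e-06, and adjusted p = 0.277 with an estimated correlation, range from 4.17e-08), with GLDC, of glycine cleavage, down 6.84-fold. The coagulation list held 8 lower and none higher of 15 genes, also when adjusted over the list alone (list adjusted p = 3.76e-08, and adjusted p = 0.341 with an estimated correlation, range from 4.77e-10). FGA fell 34.9-fold and FGG 26.7-fold. The falls without day 15 replicate 3 were 66.6-fold for FGA, 54.4-fold for FGG and 12.5-fold for CEBPA. Without knockdown replicate 1 FGA and FGG fell 19.9-fold and 13.8-fold, and without knockdown replicate 2 FGG fell 43.0-fold. The intestinal epithelium list, a marker list of another cell type, held 3 lower of 13, also when adjusted over the list alone (list adjusted p = 0.00248, and adjusted p = 0.378 with an estimated correlation, range from 3.39e-06). MEP1A and VIL1, proteins of the intestinal and renal brush border, fell 12.8-fold and 8.46-fold. The list was not called without knockdown replicate 1 (adjusted p = 0.0508).

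Other liver lists gave weaker calls or none. The list of cytochromes P450 and conjugating enzymes held 4 lower and none higher of 22, also when adjusted over the list alone, with a median log2 change of -0.0038 (list adjusted p = 0.0411, and adjusted p = 0.378 with an estimated correlation, range from 0.00443). The 4 were AKR1D1, GSTA1, SULT1E1 and NAT2. The NAT2 call was lost with a pseudocount of 1 (adjusted p = 0.0665, range over alternatives 0.0043 to 0.0665) and, at under 2-fold, with one of 64. The list call was lost without day 5 replicate 3 (0.052), day 10 replicate 2 (0.0529), day 15 replicate 1 (0.112) or knockdown replicate 1 (0.0977). It was also lost with the spike-in pair as a block (0.0595), a pseudocount of 1 (0.109), quantile normalization (0.0722), 75th percentile scaling (0.0774) and a stricter filter (0.056). The hepatoblast list held 3 lower and none higher of 15 (4 lower and 1 higher adjusted over the list alone), with a median of -0.315. Its list adjusted p was 0.0143, and adjusted p = 0.378 with an estimated correlation. Peroxisome and fatty acid oxidation (list adjusted p = 0.16) and glucose and glycogen metabolism (0.21) were not called. Of 19 cholesterol biosynthesis genes, none was called with limma, either over all genes or adjusted over the list alone, and the list median was 0.08 (list adjusted p = 0.631); 5 had an unadjusted p below 0.05. Of 30 mesenchyme and stellate genes 4 were higher and none lower (5 higher adjusted over the list alone), with a median log2 change of 0.64 (list adjusted p = 8.61e-05, and adjusted p = 0.487 with an estimated correlation, range from 8.51e-09). TWIST1, a mesenchymal transcription factor, rose 3.18-fold. Fry called neither the mesenchyme and stellate list (adjusted p = 0.203) nor the epithelial junction list (adjusted p = 0.131). The epithelial junction list held 3 lower and 1 higher of 30, also when adjusted over the list alone (median -0.26, list adjusted p = 0.00192, and adjusted p = 0.565 with an estimated correlation, range from 8.88e-05). OCLN, a tight junction protein, fell 2.58-fold and GRHL2, an epithelial transcription factor, rose 3.03-fold. NANOG, SOX17 and CXCR4 were not called, with log2 changes of 0.34 ± 0.94, -1.56 ± 0.57 and 0.11 ± 0.46 SE. SOX17 passed without day 15 replicate 1, with -2.33 and an adjusted p of 0.0101 (range over alternatives 0.0101 to 0.339).

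In the same comparison the extraembryonic and trophoblast list held 4 higher and 1 lower of 11 (5 and 1 adjusted over the list alone; list adjusted p = 0.0179, and adjusted p = 0.388 with an estimated correlation, range from 0.000824). HSD3B1, a steroid dehydrogenase of placenta, rose 5.34-fold (8.04-fold without knockdown replicate 3), and CDX2 fell 3.11-fold. That list was not called without day 15 replicate 2 (0.0577), without _x_at and _s_at probe sets (0.0777), with a stricter filter (0.13), the mean of a gene's probe sets (0.061), every probe set (0.0876) or fry (0.0741). The haematopoietic list held 3 lower and none higher of 7, also when adjusted over the list alone (list adjusted p = 0.0473, and adjusted p = 0.378 with an estimated correlation, over a range from 0.00162 to 0.606). CD163, a macrophage receptor, fell 3.14-fold and was below 2-fold with a pseudocount of 64. The haematopoietic call was lost without any one of 6 arrays, which were day 5 replicates 2 and 3, day 10 replicates 1 and 2, day 15 replicate 1 and knockdown replicate 3 (adjusted p from 0.0501 to 0.118). It was lost too under most other settings, and without _x_at and _s_at probe sets its median was 0.077 (adjusted p = 0.606). The cell cycle list was called lower with a median log2 change of -0.39 (list adjusted p = 0.0049, and adjusted p = 0.766 with an estimated correlation, range from 3.19e-05). None of its 32 genes was called with limma, also when adjusted over the list alone, and 8 had an unadjusted p below 0.05. It was not called without knockdown replicate 2 (0.106) or with fry (0.448).

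**Figure D2:**
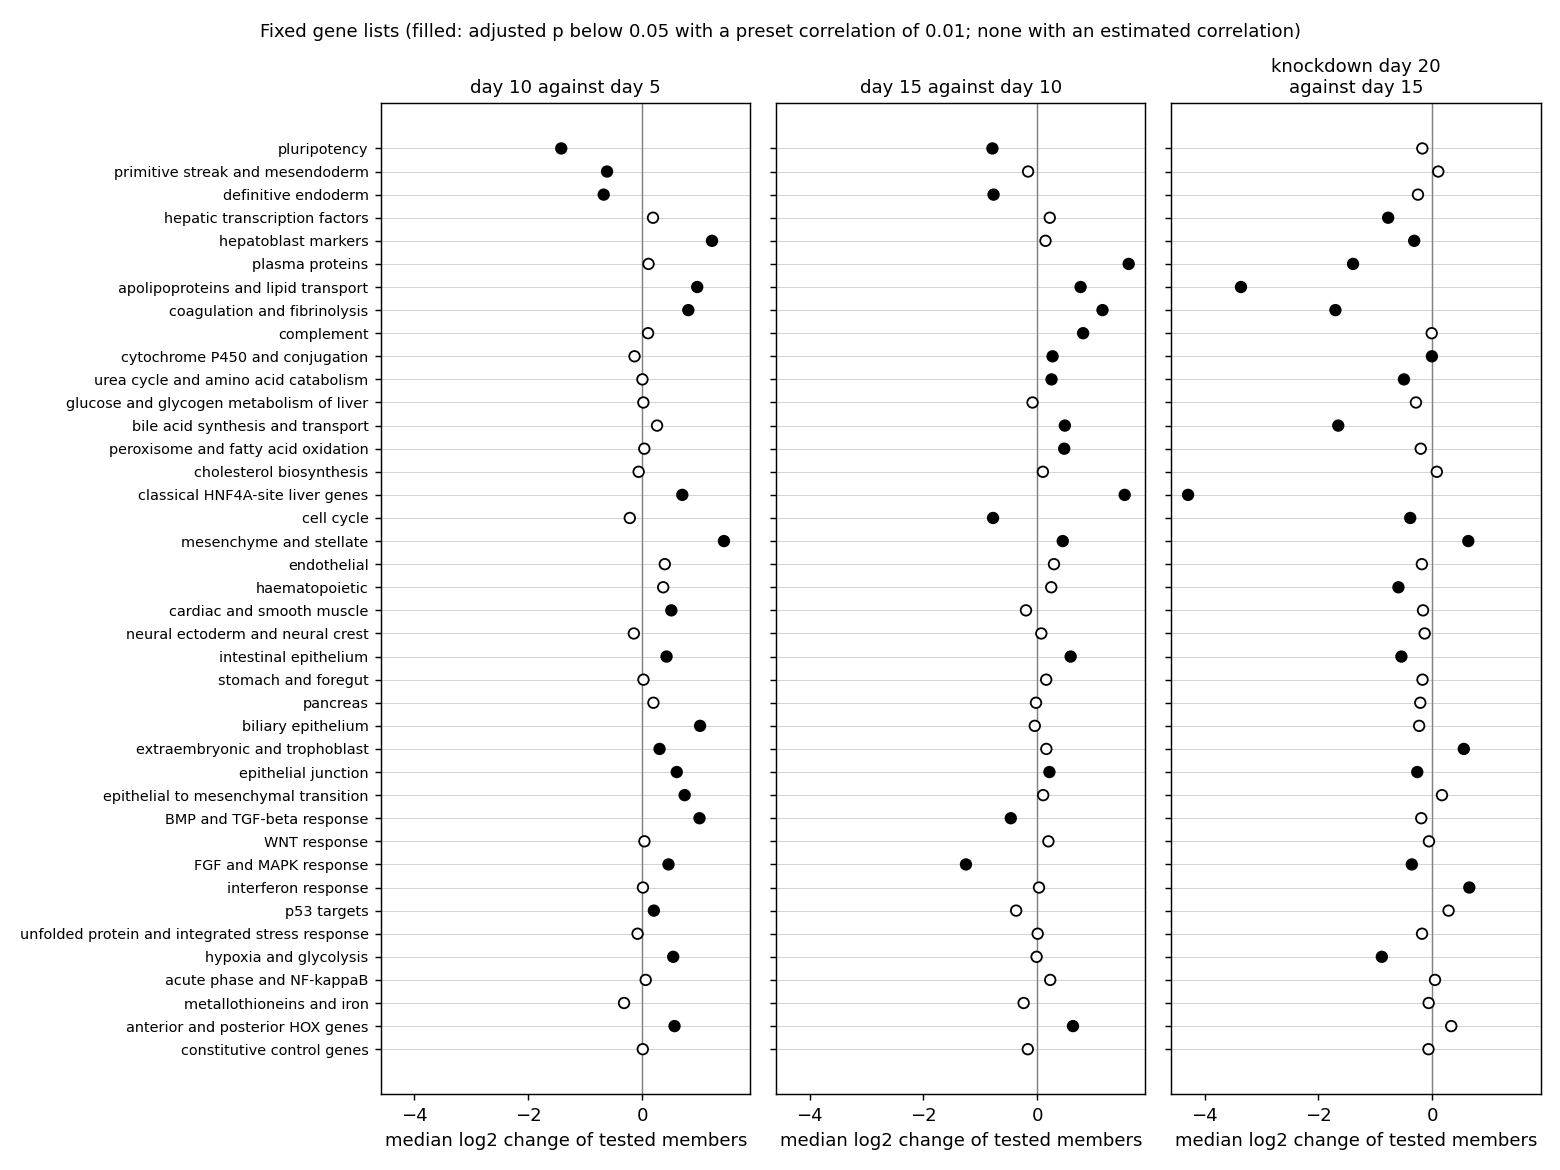
Median log2 change of the tested members of each of 40 gene lists, set one below another, in the 3 main comparisons, set side by side; filled points had a camera adjusted p below 0.05 with the preset correlation, and no list did with an estimated correlation. The lipid transport list stands at 0.97 in the first column and at -3.36 in the last.

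With the preset correlation 19 lists were called between days 5 and 10, 18 between days 10 and 15, and 18 in the knockdown comparison. Other groupings of the same 6 arrays called up to 17, 21 and 17. With an estimated correlation camera called 0 lists in each comparison, where the smallest adjusted p values were 0.277, 0.286 and 0.277, and 3, 4 and 7 lists had an unadjusted p below 0.05. Fry called 15, 10 and 14.

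The knockdown cells were also compared with unmodified cells of earlier stages. APOA1, FOXA2, SOX17 and CXCR4 were lower than at day 10, with log2 changes of -4.75 ± 0.32, -3.65 ± 0.41, -3.50 ± 0.57 and -3.27 ± 0.46 SE. AFP was higher (2.75 ± 0.92 SE, adjusted p = 0.0421). NANOG, TTR and SERPINA1 were not called, with log2 changes of -1.25 ± 0.94, -0.30 ± 0.93 and 0.40 ± 1.03 SE. In all, 1753 genes were called against day 10, 969 higher and 784 lower, a share of 55.3% higher. When each array was scaled to its 75th percentile the share was 43.9%, and the median of all genes moved to -0.13. The AFP call was lost under that scaling (2.64, adjusted p = 0.0539; range over alternatives 0.000217 to 0.184), with quantile normalization (0.0592), no filter (0.0645), only the groups compared (0.085) and no intensity trend (0.0501). It was also lost without any one of 7 arrays, which were day 5 replicates 1 and 2, day 10 replicates 2 and 3, day 15 replicate 2 and knockdown replicates 2 and 3 (adjusted p from 0.0528 to 0.184). Without knockdown replicates 1, 2 and 3 in turn AFP stood 18.5-fold, 4.33-fold and 3.81-fold higher, against 6.72-fold. Without _x_at and _s_at probe sets APOA1 was not called (-0.85, adjusted p = 0.0951; range over alternatives 2.66e-07 to 0.0951).

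Compared with day 5, APOA1, AFP and TTR were higher in the knockdown cells (2.10 ± 0.32, 4.04 ± 0.92 and 3.32 ± 0.93 SE). NANOG, SOX17, CXCR4 and FOXA2 were lower, with log2 changes of -5.12 ± 0.94, -4.34 ± 0.57, -4.26 ± 0.46 and -2.89 ± 0.41 SE. SERPINA1 was not called (0.54 ± 1.03 SE). In all, 2719 genes were called, 1524 higher and 1195 lower, a share of 56.1% higher that was 44.3% with the 75th percentile scaling, where the median of all genes moved to -0.14. The TTR call (adjusted p = 0.0124) was lost without knockdown replicate 2 or 3 (adjusted p = 0.0601 and 0.0658; range over alternatives 0.000124 to 0.0658). Without knockdown replicates 1, 2 and 3 in turn AFP was 45.3-fold, 10.6-fold and 9.34-fold higher, against 16.5-fold, and TTR 25.8-fold, 6.62-fold and 5.84-fold, against 9.99-fold. NANOG was 72.7-fold lower without replicate 1 and 18.2-fold lower without replicate 3, against 34.8-fold. Without _x_at and _s_at probe sets APOA1 was not called (0.19, adjusted p = 0.718; range over alternatives 9.28e-05 to 0.718).

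To place the knockdown cells along the course, genes were chosen by the difference between some groups and read between other groups. Of the 563 genes that rose from day 5 to day 10, 84 were lower in knockdown cells than at day 15, where 18.4 would be so by chance (two-sided Fisher's exact p = 5.79e-33), and 23 were higher, where 10.5 would be (p = 0.000384). The 23 were 15 without day 10 replicate 2. The median log2 change of all the genes that rose was -0.16, and it was -0.26 without day 15 replicate 1 and -0.0029 without day 15 replicate 2. Of the 321 that fell, 16 were higher, where 5.99 would be (Fisher's exact p = 0.000353), and 12 were lower, where 10.5 would be (p = 0.631). The 16 were 9 without day 5 replicate 1 (Fisher's exact p = 0.0389) or day 10 replicate 1 (Fisher's exact p = 0.0152). Without _x_at and _s_at probe sets 7 of those that fell were higher and 10 lower (Fisher's exact p = 0.357). Of the 1344 genes higher at day 15 than at day 5, 432 were higher in knockdown cells than at day 10, where 92.0 would be (Fisher's exact p = 3.13e-202), and 96 were lower, where 74.4 would be (p = 0.00841). The 96 were 58 without day 10 replicate 2. Of the 893 lower at day 15, 236 were lower in knockdown cells than at day 10, where 49.5 would be (Fisher's exact p = 7.2e-103), and 9 were higher, where 61.1 would be (p = 1.07e-17). The 9 were 21 without knockdown replicate 1. Genes are not independent of each other, so these p-values are too small. Both calls also come from the same fit, in which each gene's spread is estimated from all 12 arrays. Genes with a small spread are easier to call in both, so the counts given as chance may be too low.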

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

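Settings were fixed before the data were examined, except the 2 that treat the spike-in pair, day 5 replicate 3 and day 15 replicate 3, as a batch that the labels do not name. Across all settings 295 of 330 gene or list counts stayed within 1.5 times the reported count. Of values of named genes 7675 of 8394, and of called lists 1394 of 1536, kept their side of the threshold. No call reversed in its test (708 gene calls were lost and 11 gained). Some values that were not called changed sign, as did the medians of the cytochrome P450 and haematopoietic lists in the knockdown. A pseudocount of 64, which shrinks changes of weak genes by construction, gave 525 genes (day 10 against 5), 395 (day 15 against 10), 1337 (day 15 against 5), 411 (knockdown against day 15), 973 (against day 10) and 1643 (against day 5), and 134, 44 and 221 genes highest at day 5, 10 and 15. Counting every probe set, which tests more features, gave 1572, 1205, 4093, 1344, 3418 and 5236, and 413, 124 and 668. Without the 2-fold limit, which admits smaller changes, 1177, 4320, 3468 and 5147 genes were called for day 15 against 10, day 15 against 5, and knockdown against day 10 and day 5, and 440 were highest at day 5. Leaving out the spike-in pair gave 1085 for day 15 against 10 and 655 highest at day 15, and the cause was not tested.

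Leaving out 1 array at a time gave 352 to 1012 genes for day 15 against 10, 470 to 811 for knockdown against day 15, 36 to 74 highest at day 10 and 195 to 627 highest at day 15. Without probe sets whose names end in _x_at or _s_at, the genes that fell from day 5 to day 10 had a median of 0.035 in the knockdown comparison (Fisher's exact p = 0.357), and the cause was not tested. Under that setting APOA1 was read from another probe set, with log2 changes of 1.04 (adjusted p = 0.086, range over alternatives 1.18e-08 to 0.086) for day 10 against 5 and -1.16 (adjusted p = 0.0608, range over alternatives 2.88e-07 to 0.0608) for knockdown against day 15, and neither was called. Lists called fell to 0 in each of the 3 comparisons with an estimated correlation, and to 10 for day 15 against 10 with fry, which asks another question.

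Equal replicate numbers were not taken as pairs over the 12 arrays. Of 18 pairs with the same number, 6 correlated above 0.1 in their deviations (from -0.317 to 0.215), all 6 among the 9 unmodified pairs, and 3 of 12 arrays correlated best with their own number. With the replicate number as a block the counts were 910, 735, 2251, 736, 1762 and 2735 in the order above, and no count moved by over 1.5 times. For day 15 against 5 all 3 pairs were above 0.1 (0.101 to 0.215), and the block changed no call of the always-named genes there. The block ended the AFP calls of the knockdown against day 15 and day 10 (adjusted p = 0.0522 and 0.0547, ranges over alternatives 0.0217 to 0.113 and 0.000217 to 0.184). The alternatives planned for the level of HNF4A were not run, since it is not analysed here. Signal over background limits weak genes, whose changes depend on the pseudocount.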

Other observations

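The 7 tests of explanations given here for AFP and TTR, for day 15 replicate 3 and for liver mRNAs in the knockdown arrays were chosen after the results were seen; the counts over other splits of the arrays were fixed before. Genes of other lineages were also among the calls. Between days 5 and 10 the cardiac and smooth muscle list held 4 higher and none lower of 17 genes (6 higher adjusted over the list alone; list adjusted p = 0.00224, and adjusted p = 0.378 with an estimated correlation, the highest of a range over alternatives that began at 3.99e-05). They were ACTC1, a cardiac actin (26.4-fold), ISL1 (26.3-fold), TNNC1, a troponin (9.46-fold), and NKX2-5 (5.57-fold). ISL1 is also known from pancreas and neurons. The extraembryonic and trophoblast list held 4 higher and none lower of 11, also when adjusted over the list alone (list adjusted p = 0.00112, and adjusted p = 0.378 with an estimated correlation, range from 1.55e-08), with GATA3, a transcription factor of trophoblast and other tissues, up 8.41-fold and ENPEP, a peptidase, up 5.24-fold. TFAP2A, a transcription factor of neural crest and surface ectoderm, rose 23.4-fold, while its list was not called (adjusted p = 0.159) and held 1 higher and 2 lower of 14.

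In the knockdown comparison with day 15, the hypoxia and glycolysis list held 6 lower and none higher of 19 genes (9 lower adjusted over the list alone; list adjusted p = 5.09e-07, and adjusted p = 0.378 with an estimated correlation, range from 2.64e-10). ALDOC, a glycolytic aldolase, fell 7.35-fold (13.8-fold without day 15 replicate 3) and SLC2A3, a glucose transporter, 2.51-fold. The interferon response list held 6 higher and 1 lower of 24 (8 and 1 adjusted over the list alone; list adjusted p = 0.000483, and adjusted p = 0.378 with an estimated correlation, range from 8.52e-05), with IRF9, a subunit of an interferon-activated transcription factor, up 2.55-fold (below 2-fold with a pseudocount of 64, at a log2 change of 0.96). These cells differ from the unmodified cells in viral transduction and age as well as in the knockdown. KLB and FGFR4, which together bind an intestinal FGF in liver, fell 15.6-fold and 5.87-fold.

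AFP and TTR kept part of their day 15 signal above day 5 in the knockdown arrays, 15.2% and 7.63% on average, and 0.589%, 19.6% and 25.5% for AFP on replicates 1, 2 and 3. Cells that kept normal liver expression would leave other abundant liver mRNAs at about the same percent. The median of 16 others was 0.632%, and 13 of the 16 lay between -0.00678% and 3.04%, which argues against such cells as the whole source. The exceptions were SERPINF1 (440%), TFPI (88.7%) and FGB (8.86%). SERPINF1 stood above its day 15 mean, so its value is not a remainder. TFPI and FGB kept signal as well, so signal left was not particular to AFP and TTR. FGB kept 0.268%, 20.6% and 5.71% on replicates 1, 2 and 3. On replicate 1 TTR kept 0.202%, near the median of 0.115% of the other genes. Saturation of the arrays at day 15 stays open, because only APOA1 was about as bright, and 1.94% of its signal was left. No other biological explanation was tested.

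Day 15 replicate 3 differed by at least 2-fold from the mean of the other day 15 arrays in 1212 genes, 303 higher and 909 lower. Its deviation ran against the change from day 10 to day 15, with a mean slope across genes of -0.318 when no array was shared between the axes, against -0.0379 for the other pair of arrays. What the other day 15 arrays share and replicate 3 lacks enters both axes, with opposite signs. Any such part makes the slope more negative, whether or not it concerns the course, and the other pair of arrays cancels it. The slope therefore cannot show a slower course of that culture, a hypothesis found and tested on the same data, which stays open. A batch shared with day 5 replicate 3, which the labels do not name, stays open. Day 5 replicate 3 deviated in the same direction by a median of 0.237 (quartiles -0.115 and 0.657) against a median size of 1.31. The 1212 genes were chosen by their deviation on day 15 replicate 3, so a smaller one on another array follows from the choice alone. Genes near background at day 5, such as RBP4 and AHSG (mean signals 2.48 and 4.254), could hardly be lower there. A part at least may come from such a batch, since 66.4% of these genes had the same sign on day 5 replicate 3. RNA degradation stays open too, because the ratio of 3' to 5' signal on day 15 replicate 3 was the highest of all arrays for ACTB (1.43) and the lowest for GAPDH (0.949).

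Lists of lipid transport and several other liver functions were called lower in the knockdown arrays than at day 15 with the preset correlation but not with an estimated one (for lipid transport adjusted p = 0.341 with an estimated correlation, range from 2.17e-21), while those of complement, cholesterol, glucose and peroxisomes were not called. A loss of epithelial cells in general would lower the epithelial junction list by about as much as lipid transport, but its median was -0.26 (lower quartile -0.76) against -3.36. Its limits were set when both medians were already known. Scaling differences as seen at the 75th percentile are argued against too, since those signals ran only from 88.62 to 124.8 over the arrays. Scaling each array to that percentile was therefore bound to leave the lipid transport median low, and it was -3.40. A smaller share of liver cells among the epithelial cells, viral transduction and 5 more days of culture were not tested, and the last 2 are confounded with the knockdown.

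Other splits of the arrays were counted with a rule set before the splits were run. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and the real split alone gave the most genes in all 6 comparisons (value 1 in each). Day 10 against 5 gave 884 genes and at most 0 in another split, day 15 against 10 gave 718 and 0, day 15 against 5 gave 2237 and 0, and the knockdown gave 726 and 11 against day 15, 1753 and 0 against day 10, and 2719 and 0 against day 5. For the 4 sets of chosen genes, -log10 of Fisher's exact p was 32.2 and at most 0 in another split, 3.45 and 0.776, 201.5 and 0, and 102.1 and 0. Every other split but 1 of the knockdown against day 15 called 0 genes, which fixes Fisher's exact p at 1, so these values add nothing to the gene counts. Lists called were 19 against at most 17, 18 against 21 and 18 against 17, and for day 15 against 10 the real split was 1 of 4 that called at least 18. Among 100 splits of the 9 unmodified arrays into 3 groups of 3, 4 gave at least 231 genes highest in the group standing for day 5 (highest other 354), 3 at least 70 for day 10 (346) and 1 at least 386 for day 15 (236). All 3 shares are under 0.05, but only the day 15 count was also the largest of its splits, as the limit set before required. Which stage a group stands for is arbitrary, and the highest other for day 15, 236, came from the 3 day 5 arrays. These splits therefore do not set the count of any stage apart from the others. Besides the real split, only splits that kept the 3 arrays of 1 stage together gave any such gene. The other splits that reached the day 5 and day 10 counts kept the 3 day 15 arrays together under another stage's name, with 271, 354 and 305 genes in place of 231 and 336 and 346 in place of 70, which points to a structure of the arrays. This draw was corrected once, because a first version also counted renamings of the real groups, and the first version gave 4, 4 and 1.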
